A study of Mus musculus with 10 samples.

How the data were processed

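Liver RNA of 10 lactating QSi5 mice was measured on Affymetrix expression arrays, 1 array per mouse. Per the labels, 5 mice ate a diet of high glycaemic index (HGI) and 5 a diet of low glycaemic index (LGI), from pregnancy to the peak of lactation. Per the labels' protocols, RNA was taken up with an RNeasy Mini Kit and labelled with biotin in a one-cycle reaction. The authors' deposited values are log2 expression values per probe set, a probe set being the group of short probes that reads 1 transcript. RMA, which corrects the background, normalizes arrays to a shared distribution and combines the probes of a set, and R 2.6.1 are named in the submitters' processing notes. No genome build was needed, and none is given in the sources used here.

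The deposited table held 45101 probe sets. The 64 Affymetrix control probe sets were left out of the tests and 45037 were tested, with no filter on dim signals. Gene symbols came from the platform annotation and were brought up to date through gene IDs in a RefSeq gene table (assembly GRCm38.p6, used for names alone). 34945 probe sets had 1 symbol, 932 had several and were left unnamed, and 9160 had no entry. Of those with 1 symbol, 34741 had a gene ID in the RefSeq table, which changed 0 symbols, and 204 kept the platform's name. The named probe sets covered 18193 genes.

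HGI was compared with LGI with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), without covariates, and all differences are HGI minus LGI on the log2 scale. P-values were adjusted over all probe sets by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as past the threshold. Unless another test is named, every adjusted p of a gene is limma's. The labels also give an energy balance, positive on all HGI samples and negative on all LGI samples. Whether it was measured per mouse or assigned by diet is not given in the sources used here. It goes fully with the diet, so the diet and the energy balance cannot be told apart.

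Gene groups were 32 pathway lists and 15 cell type marker lists. Of their 637 genes, 566 had a probe set, and 46 lists had the 3 measured members needed for a test. The remaining list, ketone body synthesis, is not reported here. Each gene entered with its probe set of the highest mean over the 10 arrays. Lists were tested with limma's camera, which compares a list with all other genes, at its preset correlation between genes of 0.01, and adjusted over the 46 lists. Each was tested again with a correlation estimated from its own members and with fry, which tests whether members move on balance in 1 direction without comparing them with other genes. A two-sided exact permutation of the list mean over all assignments of the arrays was added after seeing the data. Member counts are given over all probe sets tested and adjusted over the list alone.

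Named genes followed a rule: in each direction the 12 genes with the largest difference among those past the threshold, filled up by smallest p where fewer passed, without symbols that are only clone or locus numbers. To these came up to 4 members of each list with a passing member, 2 members of each called list without one, and 16 genes of hepatic carbohydrate and lipid metabolism, of which 13 had a named probe set. Apart from the tests said to be added, the groups, the tests, the lists, this rule and the first set of alternatives were chosen before the data were examined.

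The procedure was tested on simulated data made from these arrays for the HGI to LGI comparison of 45037 probe sets. Of 100 probe sets changed by 2-fold, 89% were recovered, and of 100 changed by 4-fold, 100%, with 9 false calls among 198 calls. The changed probe sets were drawn from those with a mean log2 of at least 6, and noise was independent between probe sets. The shares recovered therefore do not cover dim probe sets. The real comparison gave fewer calls (29), which makes its threshold stricter than that of the simulation. In a simulation with no diet effect in which the genes of a list shared an effect of each mouse with an SD of 0.3, camera with the preset correlation called 18 of 46 lists and camera with an estimated correlation called 1.

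Alternatives were a filter for probe sets at or above the median signal, a filter for a mean log2 of at least 6, quantile normalization of the deposited values again, median centring, a variance trend with robust fitting, array weights, 1 probe set per gene, a replicate block, an unmoderated two-sample test and leaving out each array in turn. For lists they were also camera on ranks and the mean of all probe sets of a gene. Array comparisons used the 3' minus 5' difference of the Gapdh and Actb control probe sets as a sign of RNA quality. The number of arrays, 5 per group, limits the precision. Samples that share a replicate number across the diets were not treated as pairs.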

Results

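Hepatic gene expression was compared between lactating mice that had eaten diets of high or low glycaemic index since pregnancy. The mice were of the QSi5 strain. The HGI diet held 51.4% glucose by weight and 15.6 MJ of gross energy per kg, and the LGI diet held 51.4% of a starch rich in amylose and 16.3 MJ per kg. Livers of 5 mice per diet were taken at peak lactation. The question the design puts is which hepatic transcripts differ with the kind of dietary carbohydrate at this stage.

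Correlations between the 10 arrays lay between 0.986 and 0.996. Array LGI 4 had the lowest mean correlation with its own group (0.988), and HGI 1 the next lowest (0.989). The spread of values was smallest in HGI 1 (SD 2.16 on the log2 scale, against 2.26 to 2.31 for the other 9). Genes with a mean log2 of at least 6 had a median difference of -0.04, which became -0.01 when the arrays were quantile normalized again and 0.01 without HGI 1. The Gapdh 3' minus 5' difference was 0.55 ± 0.28 (SD, n = 5) in HGI and 0.59 ± 0.21 (SD, n = 5) in LGI (two-sided exact permutation p = 0.762), and for Actb the difference between diets was -0.18 (two-sided exact permutation p = 0.421).

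Among the genes past the threshold, Lepr, Serpina12, Apoa4 and Pltp were higher in HGI, and Gsta2, Cyp2d9 and Cyp2c54 were lower. Lepr, the leptin receptor, was higher in HGI (5.47 ± 0.28 against 3.33 ± 0.23 log2, SD, n = 5 each; adjusted p = 4.77e-05), and Serpina12, a secreted serpin also called vaspin, was 4.59-fold higher (adjusted p = 0.0116). The LGI level at this Lepr probe set lay below the median of every array (3.91 to 3.97 log2), so no fold is given for it, and at a probe set with measurable signal in both diets Lepr was 1.62-fold higher (5.72 against 5.03 log2, adjusted p = 0.0211). Apoa4 and Pltp, an apolipoprotein and the phospholipid transfer protein of plasma lipoproteins, were 2.12-fold and 2.14-fold higher. Gsta2, a glutathione transferase, was 2.94-fold lower in HGI (8.03 ± 0.18 against 9.59 ± 0.53 log2, SD, n = 5 each; adjusted p = 0.0211), and the cytochromes P450 Cyp2d9 and Cyp2c54 were 2.54-fold and 2.44-fold lower.

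In all, 29 of 45037 probe sets passed the threshold, 17 higher and 12 lower in HGI. Of these, 27 had 1 gene symbol and stood for 22 genes, 11 higher and 11 lower, and 2 were unnamed. The groups of 5 mice did not overlap at any of the 29, and 18 differed by more than 2-fold. Among all probe sets 1.67% separated the groups without overlap, where chance gives 0.794%, and 3397 had an unadjusted p under 0.05, where chance gives 2252.

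The genes that rose further included Slc4a1, the anion exchanger of red cells (2.57 ± 0.33, log2 difference ± SE, adjusted p = 0.0211), and Cd24a, a surface glycoprotein of developing blood cells and epithelia (2.27 ± 0.32, adjusted p = 0.0284). At these probe sets, and at that of Serpina3a, the LGI mean lay below the median of every array (3.75, 3.44 and 3.60 log2), so the sizes are uncertain. A second Cd24a probe set with brighter signal rose by 2.31 (8.02 against 5.71 log2, adjusted p = 0.0302), and a brighter one of Slc4a1 stood at 2.25 (7.06 against 4.81 log2, adjusted p = 0.0625). The remaining Slc4a1 probe set stood at -0.01 (adjusted p = 0.997) and the other of Serpina12 at 0.10 (adjusted p = 0.884). Both had means below the median of every array in either diet. Fabp5, a fatty acid binding protein, rose by 1.05 ± 0.17 (adjusted p = 0.0480) and stood at 0.56 at its brighter probe set (adjusted p = 0.158). Abhd5, the coactivator of adipose triglyceride lipase, rose by 0.77 ± 0.11 (adjusted p = 0.0302), with its other probe sets at 0.43 and 0.19 (adjusted p = 0.442 and 0.761). Serpina11 and Serpina3a rose by 1.01 and 1.00, and F11, coagulation factor XI, by 0.76. Isg20, an exonuclease, stood at 1.47 and did not pass (adjusted p = 0.0575). Lepr rose at 3 of its 4 probe sets, while the fourth, with a mean of 3.29 log2 in HGI, stood at -0.02.

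Among the genes that fell, Mmd2 fell at 1 of its 3 probe sets (-1.99 ± 0.31, adjusted p = 0.0458) and stood at -1.18 (adjusted p = 0.0575) and 0.02 at the others. Prom1 (CD133) fell by 1.54, Ildr2 by 1.05, Cryl1 by 0.97, B4galt5 by 0.89, Ppl (periplakin) by 0.83 and Ghdc by 0.46. Tdo2, the first enzyme of tryptophan breakdown, fell at 2 of its 3 probe sets, by 0.82 and 0.79, and stood at -0.59 at the remaining one (adjusted p = 0.133). The other Ildr2 probe sets stood at -0.93 and -0.18 and the other of B4galt5 at -0.03, none past the threshold. Ddah1 stood at -0.64 and did not pass (adjusted p = 0.0575). Of the 4 Cryl1 probe sets 1 passed, a second stood at -1.01 (adjusted p = 0.0727), another at -0.06 and the last at 0.31, with an SD of 1.31 in HGI.

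**Figure D1:**
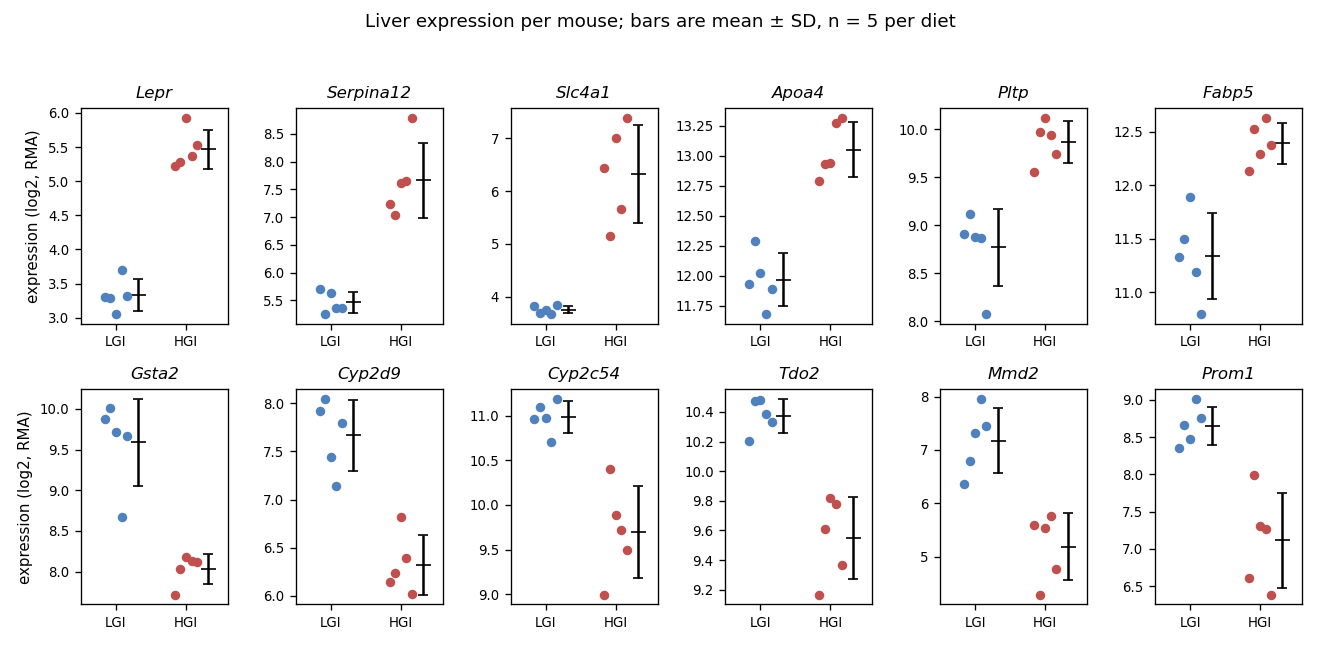
Log2 expression of 12 genes past the threshold in each mouse, LGI in blue and HGI in red, with black bars for mean ± SD (n = 5 per diet). In each of the 12 panels the groups do not overlap, with Lepr at 3.33 in LGI and 5.47 in HGI and Gsta2 at 9.59 and 8.03.

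The count moved with single arrays: it was 27 without HGI 1, 21 without HGI 2, 49 without HGI 3, 15 without HGI 4, 7 without HGI 5, 26 without LGI 1, 43 without LGI 4, and 5 each without LGI 2, LGI 3 or LGI 5. Only Serpina12 and 2 Lepr probe sets passed whichever array was left out. Median centring gave 13 higher and 4 lower, 76.5% higher, against 58.6% higher as deposited. Chance is argued against for the count of 29, since the highest count among other splits of the arrays was 1. The splits cannot tell the diet from another difference that follows the groups.

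Camera called the lists of xenobiotic and of glutathione genes lower in HGI. Both lists hold Gsta2, Gstm1 and Gstm3, so their calls are not separate results. Of the 19 measured members of the xenobiotic metabolism list, 0 rose and 1 fell (Gsta2) over all probe sets tested, and adjusted over the list alone 0 rose, 6 fell and 13 did not pass, with a mean of -0.57. The 6 were Gsta2 (-1.56), Gstm3 (-1.12), Cyp2b9 (-1.11), Cyp3a11 (-1.05), Ces2a (-0.75) and Gstm1 (-0.48). Its camera adjusted p was 1.22e-09, and the call was lost at adjusted p = 0.198 with an estimated correlation. Of 16 members of the NRF2 and glutathione list, 1 fell (Gsta2) over all probe sets tested and 10 fell adjusted over the list alone, among them Ephx1, the microsomal epoxide hydrolase (2.83-fold lower), Nqo1 (-0.73) and Gpx1 (-0.48). Its mean was -0.46 (camera adjusted p = 4.37e-08, adjusted p = 0.198 with an estimated correlation). Fry called both lists (adjusted p = 0.0400 for xenobiotic metabolism and 0.0466 for NRF2 and glutathione). Markers of Kupffer cells and of liver endothelial cells lay the other way in these livers (means 0.27 and 0.28), and HGI 1 had the narrowest spread of values.

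Camera called 4 lists of lipid and sugar metabolism higher in HGI, and neither fry nor a correlation estimated from the members called any of them. In the fatty acid synthesis list, with 17 members, 0 passed over all probe sets tested and 5 rose adjusted over the list alone: Pnpla3 (1.66), Gpam (0.66), Acaca (0.65), Fads1 (0.63) and Fads2 (0.59). The mean was 0.44 (camera adjusted p = 1.04e-09, adjusted p = 0.471 with an estimated correlation) and 0.24 without LGI 4. That array was lowest of its group in Pnpla3, at 5.51 log2 against 7.99 to 8.44 in the other LGI mice. It was also lowest in Fads1, at 11.53 against 12.11 or more, so it adds to both differences. Cholesterol synthesis and uptake genes, with 0 of 20 members past either adjustment, had a mean of 0.27 (camera adjusted p = 1.21e-06, adjusted p = 0.628 with an estimated correlation), and 0.11 without LGI 4; their leading members were Fdps (0.81, adjusted p = 0.520, and 0.49 without LGI 4) and Tm7sf2 (0.26, adjusted p = 0.579). The 11 ChREBP targets and fructose metabolism genes had a mean of 0.24 with 0 members past either adjustment (camera adjusted p = 0.0245, adjusted p = 0.657 with an estimated correlation), and were no longer called without LGI 4 (0.07, adjusted p = 0.363), without HGI 2 (0.16, adjusted p = 0.188) or without HGI 4 (0.19, adjusted p = 0.106). The 7 glycolysis genes had a mean of 0.27 with 0 past either adjustment, led by Pklr (0.88, adjusted p = 0.563, and 0.50 without LGI 4) and Pfkl (0.47, adjusted p = 0.586, and 0.26 without HGI 5). Camera called them (adjusted p = 0.0416, adjusted p = 0.487 with an estimated correlation), but not without HGI 4 (0.23, adjusted p = 0.178), HGI 5 (0.21, adjusted p = 0.0600), LGI 1 (0.27, adjusted p = 0.101) or LGI 5 (0.28, adjusted p = 0.0536). Kupffer and endothelial markers lay in the same direction (0.27 and 0.28).

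Camera called the lists of amino acid catabolism, mitochondrial fatty acid oxidation, oxidative phosphorylation and the proteasome lower in HGI, and fry called none of them. Of 20 amino acid catabolism and urea cycle genes, 0 passed over all probe sets tested at the probe set used for the list, although Tdo2 passed at its 2 dimmer ones. Adjusted over the list alone 7 fell, led by Oat, ornithine aminotransferase (-1.10), Prodh, proline dehydrogenase (-0.63) and Tdo2 (-0.59), and 1 rose, Ass1 (0.50, and 0.31 without HGI 2, where it no longer passed, adjusted p = 0.0660). The list mean was -0.26 (camera adjusted p = 1.12e-06, adjusted p = 0.529 with an estimated correlation). Of 17 mitochondrial fatty acid oxidation genes, 0 passed over all probe sets tested and 3 fell adjusted over the list alone, Acads (-0.50), Acadm (-0.41) and Etfb (-0.27). Their mean was -0.25 (camera adjusted p = 1.12e-06, adjusted p = 0.602 with an estimated correlation), and -0.16 without HGI 1. Of 25 oxidative phosphorylation genes, 0 passed over all probe sets tested and 4 fell adjusted over the list alone, Uqcrc1 (-0.35), Sdhb (-0.29), Ndufa9 (-0.29) and Ndufb8 (-0.27). Their mean was -0.15 (camera adjusted p = 9.30e-06, adjusted p = 0.602 with an estimated correlation), and -0.10 without HGI 1. All 24 proteasome genes had a value below 0, with a mean of -0.22, and 0 passed either adjustment; the leading members were Psmd14 (-0.37, adjusted p = 0.447) and Psmc3 (-0.28, adjusted p = 0.449), and camera gave adjusted p = 1.22e-09 (adjusted p = 0.487 with an estimated correlation). Without HGI 1 and LGI 4, left out after seeing the data, the proteasome mean was -0.13 and that of mitochondrial fatty acid oxidation -0.10. Kupffer and endothelial markers lay in the opposite direction (0.27 and 0.28).

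Camera called the growth hormone and IGF axis list higher, with a mean of 0.36 and a median of 0.12. Of its 12 members, 0 passed over all probe sets tested, and adjusted over the list alone 8 did not pass and 4 rose: Igfbp1, an IGF binding protein that insulin represses (2.84-fold higher), Ghr, the growth hormone receptor (1.07), and the feedback inhibitors Socs2 (0.70) and Cish (0.47). Igf1 itself stood at -0.16 (adjusted p = 0.762). Its camera adjusted p was 7.13e-05 (adjusted p = 0.0883 with an estimated correlation), and fry called it too (adjusted p = 0.0400). Erythroid, Kupffer and endothelial markers lay in the same direction (0.79, 0.27 and 0.28).

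Of the 15 marker lists camera called 3, erythroid, Kupffer and endothelial cells, all higher. The two-sided exact permutation p of the list mean was 0.0159, 0.246 and 0.0556 for these. Of 5 erythroid markers, 0 passed over all probe sets tested on the probe set used for the list, and adjusted over the list alone 2 rose, Slc4a1 (2.25) and Alas2, the erythroid enzyme of haem synthesis (1.34). The list mean was 0.79 and the median 0.26 (camera adjusted p = 1.62e-04, adjusted p = 0.198 with an estimated correlation). All 11 markers of Kupffer cells and macrophages had values above 0, with a mean of 0.27 that fell to 0.12 without HGI 5, and 0 passed either adjustment. Vsig4 (0.46, adjusted p = 0.525) and Cd68 (0.37, adjusted p = 0.698, and 0.23 without HGI 5) led them. Camera gave adjusted p = 5.81e-05 for this list (adjusted p = 0.602 with an estimated correlation). Of 10 liver endothelial cell markers, all above 0 with a mean of 0.28, 0 passed over all probe sets tested and 1 rose adjusted over the list alone, Stab2, a scavenger receptor of sinusoids (0.76). Stab1 stood at 0.25 (adjusted p = 0.631), and camera gave adjusted p = 3.33e-05 for the list (adjusted p = 0.487 with an estimated correlation).

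**Figure D2:**
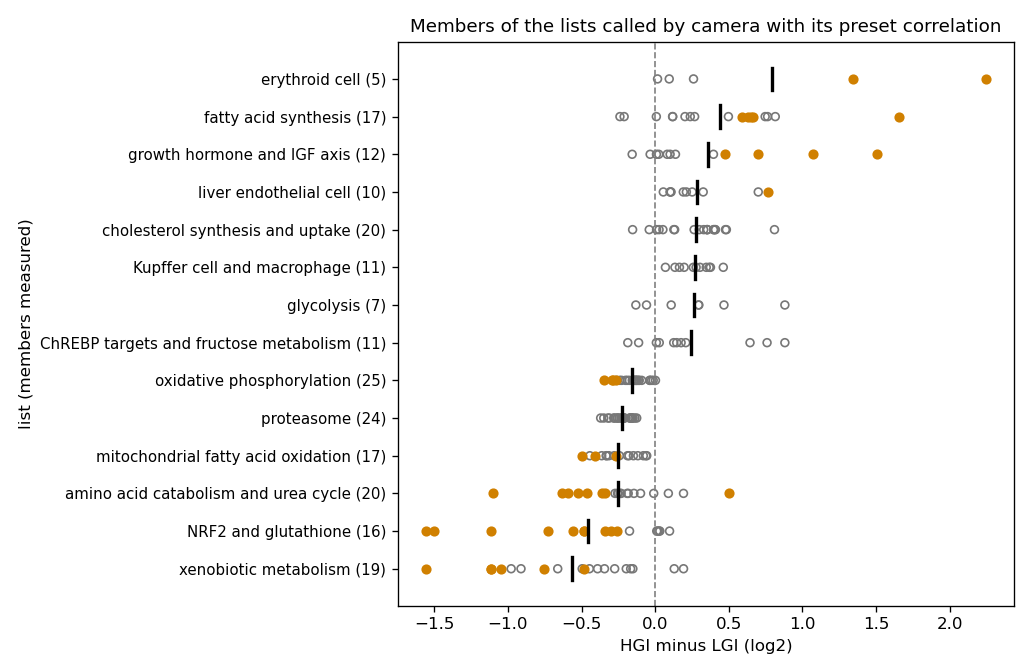
Difference between diets (HGI minus LGI, log2) of each member of the 14 lists called by camera with its preset correlation, in orange where it passed adjusted over the list alone and open where it did not, with a black line at the list mean. Means run from -0.57 for xenobiotic metabolism to 0.79 for erythroid cell markers.

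Camera with the preset correlation thus called 14 of 46 lists, 8 higher and 6 lower, and with an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.0883. By exact permutation of the list mean 11 lists had an unadjusted p under 0.05, where chance gives 2.3, and 0 passed adjustment (smallest adjusted p 0.0913). The smallest p that this permutation can give is 0.00794, so to pass over 46 lists several would have to sit at that value together. That 0 passed therefore says little. Lists that share members and mice are not independent either, so 11 against 2.3 is no test. Chance cannot be excluded for the count of 14 lists, since the highest count among other splits of the arrays was 22.

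The other 32 lists were not called, with camera adjusted p-values from 0.0570 to 0.938. Among pathway lists with members past the threshold, lipoprotein and lipid export had 16 members and a mean of 0.06. Over all probe sets tested 1 of these rose at the probe set used for the list (Apoa4), while Pltp passed only at its dimmer one, and adjusted over the list alone 2 rose (Apoa4, 0.85, and Pltp, 1.05) and 2 fell (Scarb1, -0.33, and Vldlr, -0.44). Male-predominant liver genes, 10 in number, had a mean of 0.01. Over all probe sets tested 1 fell (Cyp2d9), and adjusted over the list alone 2 fell (Cyp2d9 and Elovl3, -0.71) and 1 rose (Hsd3b5, 2.08), while Slco1a1 stood at 0.57 (adjusted p = 0.562), and at 0.32 without LGI 4. Female-predominant liver genes had a mean of -0.22. The PPARalpha targets had a mean of -0.25, which was -0.14 without HGI 1, -0.15 without LGI 4 and -0.04 without both, and members moved both ways: adjusted over the list alone 5 of 17 fell, with Cyp4a14 at -2.09 and Acot1 at -1.08, and 2 rose, Pdk4 (0.68) and Fgf21 (0.64). In the interferon response list (mean -0.06) Rsad2 rose (1.58) and Usp18 fell (-0.78) adjusted over the list alone, and in glycogen metabolism (mean 0.19) Ppp1r3g (1.31) and Gys2 (0.54) rose on the same basis. Adjusted over the list alone, Cth fell in one-carbon metabolism (-0.71), Gpt in gluconeogenesis (-0.52), Cyp3a11 among general, Oat among pericentral, and Hal (-0.47) and Ctsc (-0.61) among periportal hepatocyte genes. On that basis Mki67 (0.69) and Plk1 (0.29) rose in the cell cycle list, Igfbp1 in insulin and FoxO signalling and Fabp4 (1.08) among adipocyte markers.

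Further pathway means were -0.07 for gluconeogenesis, 0.08 for the pentose phosphate pathway, 0.05 for lipid droplet and triglyceride storage, and -0.06 for bile acid synthesis and transport. They were -0.10 for one-carbon and methionine metabolism, 0.04 for ATF4 and amino acid response, -0.12 for endoplasmic reticulum chaperones and 0.09 for insulin and FoxO signalling. The circadian clock list stood at -0.16, heat shock at -0.19, cell cycle at -0.02, cytosolic ribosomal proteins at 0.03, and extracellular matrix and fibrosis at 0.03. The acute phase response list had a mean of -0.38 with LGI 4 and 0.13 without it, where camera called it higher (adjusted p = 6.08e-06). Marker means were -0.18 for general hepatocytes, -0.07 for pericentral and -0.10 for periportal hepatocytes, 0.15 for stellate cells, -0.06 for cholangiocytes, 0.17 for B and plasma cells, -0.02 for T and natural killer cells and -0.02 for neutrophils. Markers of adipocytes stood at 0.17, pancreatic acinar cells at -0.00, skeletal muscle at -0.06 and mammary epithelium at -0.07. Camera direction differed in sign from the mean for 6 of these (lipid droplet, male-predominant, cell cycle, neutrophil, pancreatic acinar and mammary) and from the median for 4 (insulin and FoxO, cell cycle, general hepatocyte and adipocyte).

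Means of lists that were not called on all arrays also moved with single arrays. Without LGI 4 the mean was 0.25 for neutrophil markers, 0.08 for the interferon response, -0.00 for endoplasmic reticulum chaperones, -0.17 for bile acid synthesis and transport and -0.09 for male-predominant genes. It was 0.05 for bile acid synthesis without HGI 1 and 0.05 for B and plasma cells without HGI 5. Glycogen metabolism and stellate cells were at 0.11 and 0.07 without LGI 4, and heat shock at -0.11 without HGI 2. Over the 10 arrays left out in turn, female-predominant genes ranged from -0.41 to -0.14, pericentral hepatocytes from -0.24 to 0.01, extracellular matrix from -0.05 to 0.09, gluconeogenesis from -0.16 to -0.02 and lipid droplet genes from 0.01 to 0.11. Some uncalled lists were called when 1 array was left out. Without LGI 4 camera called gluconeogenesis (-0.16), one-carbon metabolism (-0.15), female-predominant genes (-0.41), heat shock (-0.21), pericentral (-0.24) and periportal hepatocytes (-0.12) and extracellular matrix (0.08), and in all 21 lists. Glycogen metabolism was called without HGI 1 (0.26), HGI 5 (0.19), LGI 2 (0.23), LGI 3 (0.22) or LGI 5 (0.23), and heat shock without HGI 4 (-0.28) or HGI 5 (-0.23). Stellate cells and extracellular matrix were called without HGI 3 (0.22 and 0.09) or LGI 2 (0.22 and 0.09), gluconeogenesis also without HGI 3 (-0.12), ribosomal proteins without HGI 1 (0.08), and B and plasma cells without HGI 2 (0.24).

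None of the 13 measured genes of carbohydrate and lipid metabolism named in every case passed over all probe sets tested. The lipogenic enzymes Fasn and Scd1 stood at 0.50 (adjusted p = 0.655) and 0.12 (adjusted p = 0.827), and the regulators Srebf1 and Mlxipl at -0.24 (adjusted p = 0.884) and 0.13 (adjusted p = 0.944). The gluconeogenic genes Pck1 and G6pc stood at -0.18 (adjusted p = 0.759) and 0.76 (adjusted p = 0.759). Values were 0.03 for Txnip, a transcript induced by glucose, -0.06 for Cpt1a and 0.33 for Cyp7a1, the first enzyme of bile acid synthesis. Without LGI 4 Cyp7a1 stood at -0.46, G6pc at 0.27 and Fasn at 0.25. Over the 10 arrays left out in turn values ranged from -0.38 to -0.04 for Srebf1, -0.04 to 0.30 for Mlxipl, -0.08 to 0.11 for Txnip, -0.17 to 0.05 for Cpt1a, -0.24 to -0.11 for Pck1 and 0.07 to 0.15 for Scd1.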

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

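All tests of explanations in this part were chosen after the results they bear on had been seen. Within each group of 5 mice the most extreme value was set against the others (gap to its neighbour over the range, Dixon's 95% critical value 0.71) for 71 named values, 46 list means and 8 array measures. Of the 250 groups, 23 passed, where chance gives about 1 in 20 (12.5), and 16 of the 23 were array LGI 4.

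LGI 4 was lowest of its group in Gsta2 (ratio 0.745), Pklr (0.875), Fads1 (0.805), 1 Tdo2 probe set (0.746), Slco1a1 (0.800), Fasn (0.875) and Cyp7a1 (0.736). It was also lowest in the means of fatty acid synthesis (0.897), ChREBP targets and fructose metabolism (0.856), bile acid synthesis and transport (0.722) and male-predominant liver genes (0.776), in its mean correlation with its group (0.848) and on the first principal component (0.954). It was highest in the means of acute phase response (0.925), interferon response (0.902) and neutrophil markers (0.973). HGI 1 was lowest of its group in the NRF2 and glutathione mean (0.858), in the SD of its values (0.736) and in its mean correlation with its group (0.751). HGI 5 was highest in Pfkl (0.777) and in Kupffer cell and macrophage markers (0.736), HGI 4 was highest in Ghdc (0.759), and LGI 5 was lowest in Pltp (0.758).

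In LGI 4 the acute phase genes stood far above the other mice: Saa2 was at 14.37 log2 against 6.02 to 6.85 in the other LGI mice, Lcn2 at 13.38 against 6.65 to 7.89, and the median deviation of the 20 acute phase genes was 1.38, outside the range of 10000 random lists matched on expression (-0.51 to 0.31). This shows that these genes stand apart from others of that array. LGI 4 also had the highest Actb 3' minus 5' difference of all 10 arrays (2.27 log2) and the highest for Gapdh in LGI (0.87). HGI 5 had a higher Gapdh difference (0.99) and LGI 5 an Actb difference of 2.11, and their acute phase deviations were 0.03 and -0.08. An array with a higher Gapdh difference and another with a close Actb difference thus lacked the acute phase rise. Neither reached LGI 4 on both controls, so these values cannot decide on RNA quality as its source. For other genes of LGI 4 RNA quality stays open as well. A mouse of the HGI diet under an LGI label is argued against at the 43 probe sets called without LGI 4. Its distance from the HGI mean was 0.669 there, on a scale that is 1 at the LGI mean. Each HGI array was placed in the same way at the probe sets called without that array, 7 to 49 in number. None of them lay further than 0.448 from its own group, but the probe sets differ between these comparisons. HGI 1 had high Saa2 (9.16) and Cxcl1 (10.52) too. An acute phase response of these mice may be the source, but the design has no group for it, and no biological explanation was tested.

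Erythroid transcripts were higher in HGI, with a list mean of 0.79 but a median of 0.26. The list held 8 genes, of which 5 were measured. Of these only Slc4a1 passed over all probe sets tested, at 1 of its 3 probe sets. Alas2 stood at 1.34 (adjusted p = 0.262) and Tfrc at 0.26 (adjusted p = 0.898). Outside the list Slc25a37 stood at 1.06, Bpgm at 0.86 and Car2 at 0.62, none of them passing. Cd24a, found on developing blood cells but also on epithelia, passed at 2 of its 3 probe sets. Blood left in the tissue could give such a rise. The 21 measured leukocyte markers had a mean of 0.0362 (95% interval -0.24 to 0.31, two-sided exact permutation p = 0.730), but only 2 of them had a mean log2 of at least 6, so their level is too near the floor to decide. More circulating young red cells, or blood formation in the liver, was not tested and stays open beside the diet itself.

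The 32 xenobiotic and glutathione genes had a mean of -0.47. A lower share of hepatocytes as the whole cause is argued against, with all arrays, by 46 other hepatocyte genes of mid-range signal. Their mean was -0.0714 (95% interval -0.31 to 0.17) and differed from that of the 32 (two-sided exact permutation p = 0.00794, the smallest possible). The 32 were taken up because their lists had been called lower, so this p is not independent of that call. The test was not run without LGI 4. There the lists that gave the 46 had means from -0.24 (pericentral hepatocytes) to 0.07 (lipoprotein and lipid export). Xenobiotic metabolism stood at -0.60 and NRF2 and glutathione at -0.46 without that array. Kupffer and endothelial markers lay above 0 in HGI. The narrower spread of HGI 1 is argued against as the whole cause by -0.374 (95% interval -0.50 to -0.25) without it. A difference in RNA quality stays open: with the Gapdh covariate the mean was -0.478 (95% interval -0.72 to -0.23), but the difference of that covariate between the diets was -0.04 (95% interval -0.40 to 0.32) and it had p under 0.05 at 6.74% of probe sets, where chance gives 5%, so the adjustment could hardly move the mean. The diet, the energy balance that goes with it and any difference in handling between the groups stay open as well.

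Chance is argued against for the count of probe sets by 100 splits of the 10 arrays into 5 and 5, drawn from 126 with the real one included. Only the real split gave as many as 29, and the highest of the others was 1. With so few splits chance is made unlikely rather than excluded, and another difference that follows the groups could give the same result. Chance cannot be excluded for the number of lists called by camera with the preset correlation: 24 of the 100 splits gave at least the real 14, and the highest of the others was 22.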

How the results depend on the processing

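The removal of 2 arrays, the Gapdh covariate and the exact permutation of list means were chosen after seeing the data. The cause of a moved value was not tested unless the setting itself gives it. The count of 29 probe sets (17 higher, 12 lower) became 63 (36 and 27) with quantile normalization again, 17 (13 and 4) with median centring, 64 (34 and 30) with array weights, 58 (35 and 23; 19 shared) without HGI 1 and LGI 4, 51 (27 and 24; all 29 kept) with the Gapdh covariate, and 1 (1 and 0) with an unmoderated two-sample test, which lacks the shared variance estimate. Among probe sets with a mean log2 of at least 6, where fewer were tested, 19 were lower. Leaving out 1 array each gave 5 to 49, with 5 to 23 higher and 0 to 28 lower. The 14 called lists became 0 with an estimated correlation, 3 with fry and 0 with exact permutation of the list mean, and 13 to 21 under the other settings, leave-one-out included (13 to 21). The 0 by exact permutation says little, since its smallest possible p is 0.00794. Camera's direction for the acute phase list reversed, with a mean of -0.38 on all arrays, -0.00477 without HGI 1 and LGI 4 and 0.131 without LGI 4, in a leave-one-out range of -0.54 to 0.13. Replicate numbers do not pair the mice (correlations of deviations -0.053 to 0.069, and 0 of 5 HGI arrays closest to their own number); with a replicate block 33 probe sets passed (20 higher, 13 lower; 18 shared) and 16 lists. Of the 23 named values past the threshold, 23 passed with array weights, quantile normalization again or the Gapdh covariate, 18 with trend and robust fitting, 15 without HGI 1 and LGI 4, 14 with the replicate block, 13 with median centring and 1 with the unmoderated test. It was 3 to 20 with 1 array left out, and 6 of 14 by the mean of the gene's other probe sets. None reversed under any setting. Of 71 calls of list members over the list alone, 48 to 70 were kept with 1 array left out; 14 sign changes of named values and 63 of list values concerned values past the threshold in neither setting. Arrays correlated more within than between diets by 9.45e-04, and by 0.00231 among probe sets at or above the median signal. Dim signals limit genes near the array's floor, such as most leukocyte markers.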

Other observations

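All tests in this part were chosen after the results had been seen. Genes sharing a symbol stem were grouped where their mean log2 was at least 6, in 18 families with two-sided exact permutation of the family mean. Of 7 Serpina genes, 6 lay above 0 in HGI, with a mean of 0.70 (exact permutation p = 0.00794, adjusted p = 0.0476). Serpina6, which encodes corticosteroid-binding globulin, stood at 1.54 (adjusted p = 0.246 over all probe sets), beside Serpina12 (2.20) and Serpina11 (1.01). Serpina1b, Serpina1c, Serpina10 and the acute phase gene Serpina3n lay near 0, the last slightly below it. The 4 Fabp genes lay above 0, with a mean of 0.56 (exact permutation p = 0.0159, adjusted p = 0.0476), led by Fabp4 (1.08, adjusted p = 0.276). Serpina12 and Serpina11 had already passed over all probe sets tested, as had Fabp5 at its dimmer probe set. No test of either family without these genes was run, so the 2 family p-values are not independent of those calls. The family means kept their direction with quantile normalization again (0.72 and 0.59) and without HGI 1 (0.67 and 0.60).

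Of 76 mitochondrial ribosomal protein genes (Mrp symbols), none of them in a list, 72 lay below 0, as did 38 of 40 Nduf genes of respiratory complex I, 43 of 47 Psm genes of the proteasome and 17 of 18 Gst genes. Aldehyde dehydrogenase genes (Aldh) lay below 0 in 11 of 13 cases, led by Aldh1a1 (-0.74, adjusted p = 0.161), with a family mean of -0.22 (exact permutation p = 0.0238, adjusted p = 0.0536). Of the 18 families, 6 passed adjustment (Cyp4, Psm, Nduf, Mrp, Serpina and Fabp, each at adjusted p = 0.0476). Cyp4 (mean -0.53) rested on Cyp4a14 (-2.09), since the 4 members outside the lists had a mean of -0.14 (exact permutation p = 0.421).

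A hypothesis is that the falls of the fixed lists extend to whole families, which was tested on members outside every list. These members are among those counted above, on the same arrays, so the test is not independent of those counts. Gst members outside had a mean of -0.284 (14 genes, exact permutation p = 0.0476) and Nduf members -0.185 (32 genes, exact permutation p = 0.0159), which is consistent with wider falls, whereas Psm members outside, at -0.116 (23 genes, exact permutation p = 0.0714), leave it open. For the Mrp genes (mean -0.174, exact permutation p = 0.0159) no such test exists, since none of them is in a list and the value is that of the family itself. After adjustment over the 16 families with at least 3 members outside the lists 0 passed (smallest adjusted p = 0.0847). The smallest possible p of the exact permutation, 0.00794, limits this adjustment as well. With quantile normalization again the means were -0.24, -0.13, -0.13 and -0.08 for Gst, Nduf, Mrp and Psm, so part of the smaller shifts goes with the distribution of the values, and HGI 1 carried part of them too (-0.20, -0.13, -0.10 and -0.05 without it).

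Lepr, Igfbp1, Fgf21 and Pdk4 are transcripts that fasting raises in mouse liver, and all 4 stood above 0 in HGI, although of these only Lepr passed over all probe sets tested. A fasting-like state of the HGI livers might be proposed. It predicts a rise of PPARalpha targets and mitochondrial fatty acid oxidation genes, whose 31 members apart from Fgf21 and Pdk4 had a mean of -0.318 (95% interval -0.69 to 0.06, two-sided exact permutation p = 0.0794). Without HGI 1 it was -0.21 (95% interval -0.55 to 0.12) and without HGI 1 and LGI 4 -0.14 (95% interval -0.45 to 0.17). Each of these means lay below 0, but intervals that reach above 0 leave the question open. The labels give all HGI samples a positive energy balance, which does not speak for fasting. Whether that balance was measured per mouse is not given.

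LGI 4 also had the lowest Car3 (9.61 log2 against 12.51 to 13.04 in the other LGI mice) and Pnpla3 (5.51 against 7.99 to 8.44), and high Cd14 (10.92 against 6.01 to 6.72) and Socs3 (10.03 against 5.43 to 6.55). In this array 342 genes differed by over 2-fold from the median of its group, against 12 to 19 in the other LGI arrays and 42 to 119 in the HGI arrays.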
